A study of Mus musculus with 27 samples.

How the data were processed

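The series measured gene expression in fetal mouse lung on Illumina bead arrays, 27 arrays in all. The labels place 9 arrays in each of 3 groups, as 3 biological replicates with 3 technical arrays each, and give every sample as the left lung lobe of male fetuses at day 18 of gestation. The labels call each array a pool and do not say how many fetuses a pool held. RNA was extracted with Trizol and cleaned on a PureLink kit with DNase treatment, and biotinylated cRNA was made with an Ambion MessageAmp kit, per the labels' protocols.

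The values came from 2 tables. The intensity values in the non-normalized table are the mean bead signal of each probe on each array, which the authors deposited without normalization, and the lowest signal on any array was 84.0, so no background had been subtracted. Its detection p-value column per array, named so per the file headers, sets each probe against the negative controls of the array. The scanner software and its version are not given in the sources used here. The authors' processed matrix holds intensity on a linear scale as well: its column medians ranged from 138.4 to 138.6, every column ranked the probes as the non-normalized values did (Spearman correlation 1), and the columns shared their quartiles, so its values were quantile normalized between arrays with no background subtraction and no centring of genes. Its tool is not given in the sources used here, and no ratio is involved, so its direction is known. All columns of values were mapped to a sample.

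Probes were named from the platform's annotation. Of 45281 probes, 34885 had 1 gene symbol, 18 had several and 10378 had none, and no gene was named from a probe with several. Symbols were checked against a RefSeq table of assembly GRCm38.p6, used for names alone, and 34807 probes matched it by gene identifier. The array tables name no genome build, so no coordinates are given.

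The non-normalized signals were background corrected, quantile normalized and put on the log2 scale with neqc in limma 3.58.1 (R 4.3.3), which estimated the background from the detection p-values and added an offset of 16. A probe was kept when its detection p was under 0.05 on at least 6 of the 9 arrays of at least 1 group, which left 22958 probes. The 3 technical arrays of a biological replicate were then averaged, so that n = 3 pools per group in the main fit. A linear model over all 3 groups (limma's lmFit and eBayes, 6 residual and 2.41 prior degrees of freedom) gave 3 contrasts, each adjusted by the Benjamini-Hochberg method over all kept probes at a threshold of 0.05. P-values in the text are limma's adjusted two-sided values unless another test is named. The labels do not say how days of gestation were counted in mated and in recipient females, nor whether arrays of all groups were run together, and the sample records of EG in vivo are numbered apart from those of the other groups. Nothing in the labels says that pools came from separate litters or days, and the p-values of single probes measure the spread between these pools. The number of arrays limits the precision of every value.

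For genes with several kept probes, the probe with the highest mean was used, giving 11945 genes. Probes of 1 gene passed the threshold in opposite directions for 24 of 4908 genes with several kept probes in the EG in vitro comparison with controls and for 19 in the EG in vivo comparison, none of them named here. A probe detected on none of the 9 arrays of a group has only a bound there: the fold is then given as "at least", from the bright group's mean against the mean, over the dim group's arrays, of the higher of the lowest detected signal and the probe's own value. A named gene that its dimmer group detected on 1 to 5 of 9 arrays is given in the same way with that number, a choice made after the values had been seen, and no fold is given where the bound is under 1. Medians "at the bound" move the members detected on no array. With those on 1 to 5 arrays moved too, medians against controls shifted by at most 0.38, in the club cell list. Fold changes near the detection limit depend on the offset.

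The genes named were set by a rule. In each contrast these were the 10 highest and 10 lowest log2 fold changes among genes past the threshold whose 3 pools in 1 group all lay above the 3 of the other, leaving out clone and model names. Where fewer than 5 genes passed in a direction, the 5 with the lowest p were given as not passing. In each gene list up to 4 members with the largest change among those that passed were named, or among all members where none passed. Xist and the Y-linked genes were given as a check of the sex label. Genes of the growth-decline and globin sets of the closing section were named in addition, and X-escape genes are given there as an average. Members whose call was lost on leaving out 1 pool were mostly left unnamed.

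Gene lists were tested with camera in limma at its preset correlation of 0.01, adjusted over the 33 lists with at least 5 measured genes. They were tested again with an estimated correlation and with fry. At the preset correlation camera sets the genes of a list against all other genes. Its p-values then take genes as the units and do not measure the spread between pools alone. The lists were written from general knowledge and not from a published set, and most members of the liver, heart and skeletal muscle lists can also be expressed at a low level in lung or come from neighbouring tissue. A list is called by camera unless fry is named. Of 957 genes placed in 36 lists, 752 entries were measured, and 22 of 730 measured genes stood in more than 1 list. The lists were alveolar type I, alveolar type II and surfactant, club cell, ciliated cell, neuroendocrine cell, mesenchyme and fibroblast, smooth muscle and elastic fibre, endothelium, mesothelium, cartilage, macrophage and monocyte, granulocyte, erythroid cell, liver, heart muscle, skeletal muscle, cell cycle, DNA methylation and chromatin, imprinted gene, growth factor and lung branching signalling, glucocorticoid response, ion and fluid transport, antioxidant and redox, oxidative phosphorylation, glycolysis, hypoxia response, cholesterol and fatty acid synthesis, unfolded protein and integrated stress response, heat shock response, cytosolic ribosomal protein, interferon response, immediate early response and circadian clock. The lymphocyte, neuron and Schwann cell, and stratified epithelium of oesophagus or skin lists had 3 measured genes each and were not tested. The groups, tests, gene lists, naming rule and most alternatives were chosen before the data were examined.

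Replicate numbers 1 to 3 come from the labels of all 3 groups. Pools with the same number deviated together from their group means, with correlations across probes between 0.503 and 0.827 for every pair. A fit with the replicate number as a block was therefore run. Replicates 1 and 2 of different groups also correlated, at 0.346 or higher. The values thus set replicate 3 apart but do not show that replicates 1 and 2 are paired by number. Correlations between different numbers ranged from -0.814 to 0.774, and 6 of 9 pools correlated best with their own number. The alternatives were no background correction, median scaling, the authors' normalized values, no filter or a stricter filter on dim probes, the replicate block, arrays with the pool as a random block, arrays as independent, fits of 2 groups only, trend and robust variances, array weights, a minimum fold change of 1.5, limma's treat at a fold of 1.2, 1 probe per gene, and leaving out each pool in turn. Fits of replicates 1 and 2 only and of bright or dim arrays as a block were added after the data had been seen. A slide block was not run because no slide is named in the sources used here.

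The linear model was tested on simulated normalized pool values with independent noise and 200 of 22958 probes changed. Normalization, filtering and averaging were not part of that test, and neither were the deviations shared by pools of 1 number. In the real comparisons with controls 40.5% and 39.2% of probes were called, so the recoveries below need not hold there. In the simulated comparison of EG in vitro with control, 4.48% of probes changed by 0.5 on the log2 scale were recovered, 52.2% of those changed by 1 and 83.3% of those changed by 2, with 9 false calls. For EG in vivo with control these were 4.48%, 43.3% and 90.9% with 2 false calls, and for EG in vitro with EG in vivo 2.99%, 41.8% and 84.8% with 3 false calls. Figures were drawn with matplotlib 3.10.9.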

Results

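Expression of 45281 probes was measured in the left lung lobe of male mouse fetuses at day 18 of gestation, shortly before birth. Control fetuses developed in naturally ovulating females. Fetuses of the EG in vitro group came from blastocysts derived in vitro and transferred to pseudopregnant recipients, that is, females made receptive by mating without conception. Fetuses of the EG in vivo group came from transferred blastocysts that had developed in vivo. Each group had 3 pools with 3 technical arrays each. Between 19762 and 23449 probes were detected per array, and median signals ranged from 113 to 170 before normalization.

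The pools separated first by group, with 63.5% of the variance on a component that set controls apart from both transfer groups, and 26.7% on the next, which set replicate 3 of every group apart from replicates 1 and 2. Replicate 3 of every group was dimmer than replicates 1 and 2, with a mean median signal of 122 in controls, 117 in EG in vitro and 122 in EG in vivo against 145 to 167 for the other pools. Technical arrays of 1 pool correlated at 0.989 to 0.996. The median SD between pools of a group, each the mean of 3 technical arrays, was 0.241 on the log2 scale. It was 1.73 times that between single technical arrays of a pool (0.139), so the units differ. The variance between pools lay above the technical variance divided by 3 for 95.9% of probes. The Y-linked genes Eif2s3y, Kdm5d and Uty were detected on all arrays, with Eif2s3y between 10.42 and 11.53 on the log2 scale. Xist, the RNA that silences an X chromosome in females, stood at 10.90 in control replicate 1. It was also detected, dimly, on all 3 arrays of EG in vitro replicates 1 and 2, at 5.45 and 5.41. The remaining pools detected it on 0 arrays, at values between 4.56 and 4.83.

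**Figure D1:**
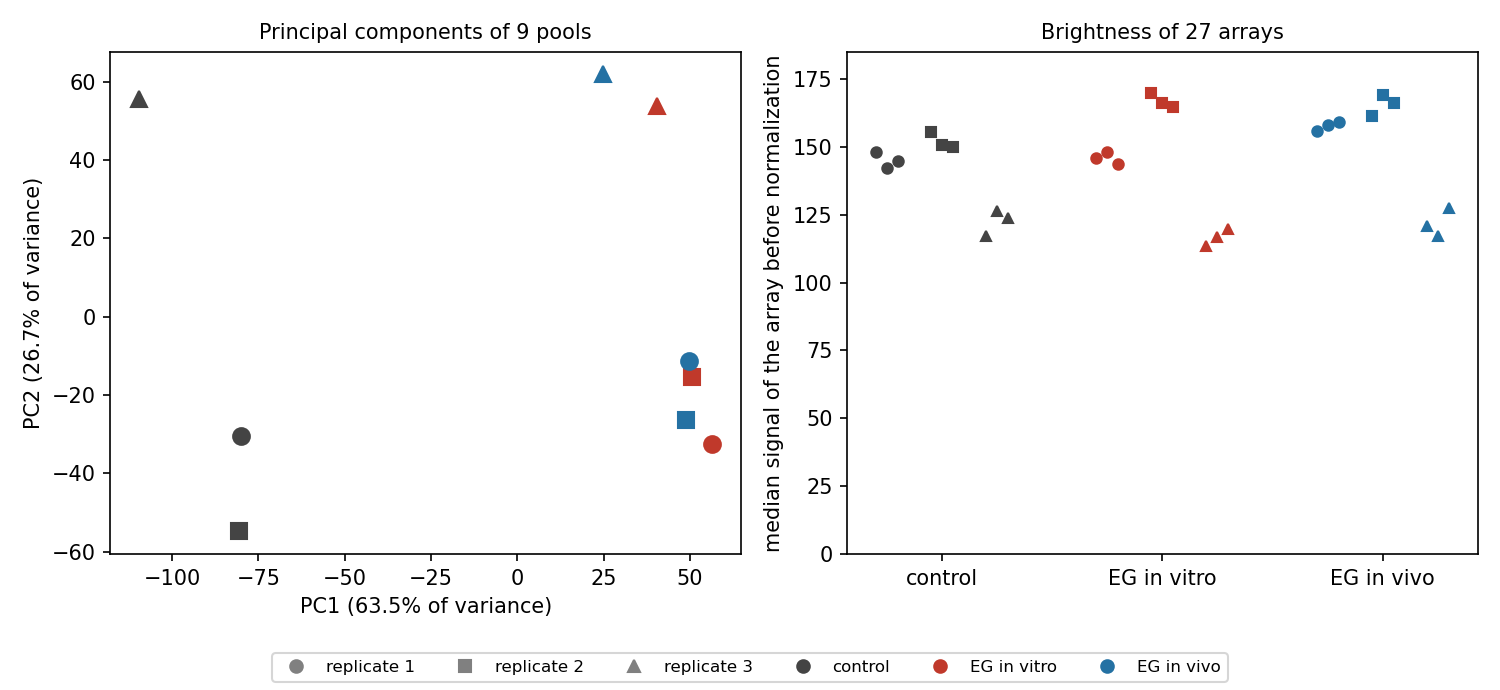
Left, principal components of the 9 pools, with the share of variance on each axis. Right, the median signal of each of the 27 arrays before normalization, on a linear scale, with symbols for replicate numbers and colours for groups. Replicate 3 lies between 113 and 127 in all groups.

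The comparison of EG in vitro with control carries culture of the embryo together with transfer to a recipient. Genes of the differentiated lung epithelium were far lower in EG in vitro lungs, and genes of dividing cells and embryonic globins were higher. Scgb1a1, the secretoglobin of airway club cells, fell by 8.20 ± 0.53 on the log2 scale (SE, n = 3 pools per group, adjusted p = 1.32e-05). Its control level of 14.87 lay close to the highest value on any array (15.11), where signals can level off, so the fall is a lower limit if they do. Sftpd, which encodes surfactant protein D, fell by 7.62 ± 0.44 (adjusted p = 8.25e-06), and Aqp5, the water channel of alveolar type I cells, detected on 1 of 9 EG in vitro arrays, was at least 86.5-fold lower (adjusted p = 2.88e-06). Chil1, a chitinase-like secreted protein, was detected on all 9 control arrays and on 0 of 9 EG in vitro arrays, which makes it at least 291-fold lower (adjusted p = 1.35e-06). Hbb-y, an embryonic beta-like globin, rose by 4.66 ± 0.23 (adjusted p = 4.52e-06).

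In all, 4728 probes rose and 4564 fell in EG in vitro, 40.5% of those tested. At least 2-fold, 1884 rose and 2335 fell. All 3 pools of 1 group lay above the 3 of the other for 53.0% of probes, where chance gives 10%. The total of 9292 became 17937 with array weights, 14788 with arrays taken as independent and 6146 when a change beyond 1.2-fold was tested. Besides those above, the lowest genes were Inmt (-7.66 ± 0.33), a methyltransferase abundant in lung, Pon1 (at least 94.0-fold lower), a paraoxonase, Chia1 (-6.25 ± 0.31), acidic chitinase, Lcn2 (at least 40.8-fold lower), an iron-siderophore binding protein, Car4 (at least 40.4-fold lower), a carbonic anhydrase, and Gjb6 (at least 39.3-fold lower, detected on 1 array), a connexin. The highest were Septin3 (at least 14.1-fold higher, detected on 3 control arrays), a septin, and Lin7a (at least 14.8-fold higher, detected on 5 control arrays), a scaffold of cell junctions. Others were Cldn6 (3.94 ± 0.29), a claudin of embryonic epithelia, Pclaf (3.73 ± 0.35), a PCNA-associated factor, Cfi (3.55 ± 0.12), complement factor I, and Dctd (3.39 ± 0.17), dCMP deaminase. Adamts18, a secreted metalloprotease, was at least 10.2-fold higher, and Col2a1, type II collagen of cartilage, at least 8.17-fold higher. All of these kept their call and direction in every alternative fit.

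**Figure D2:**
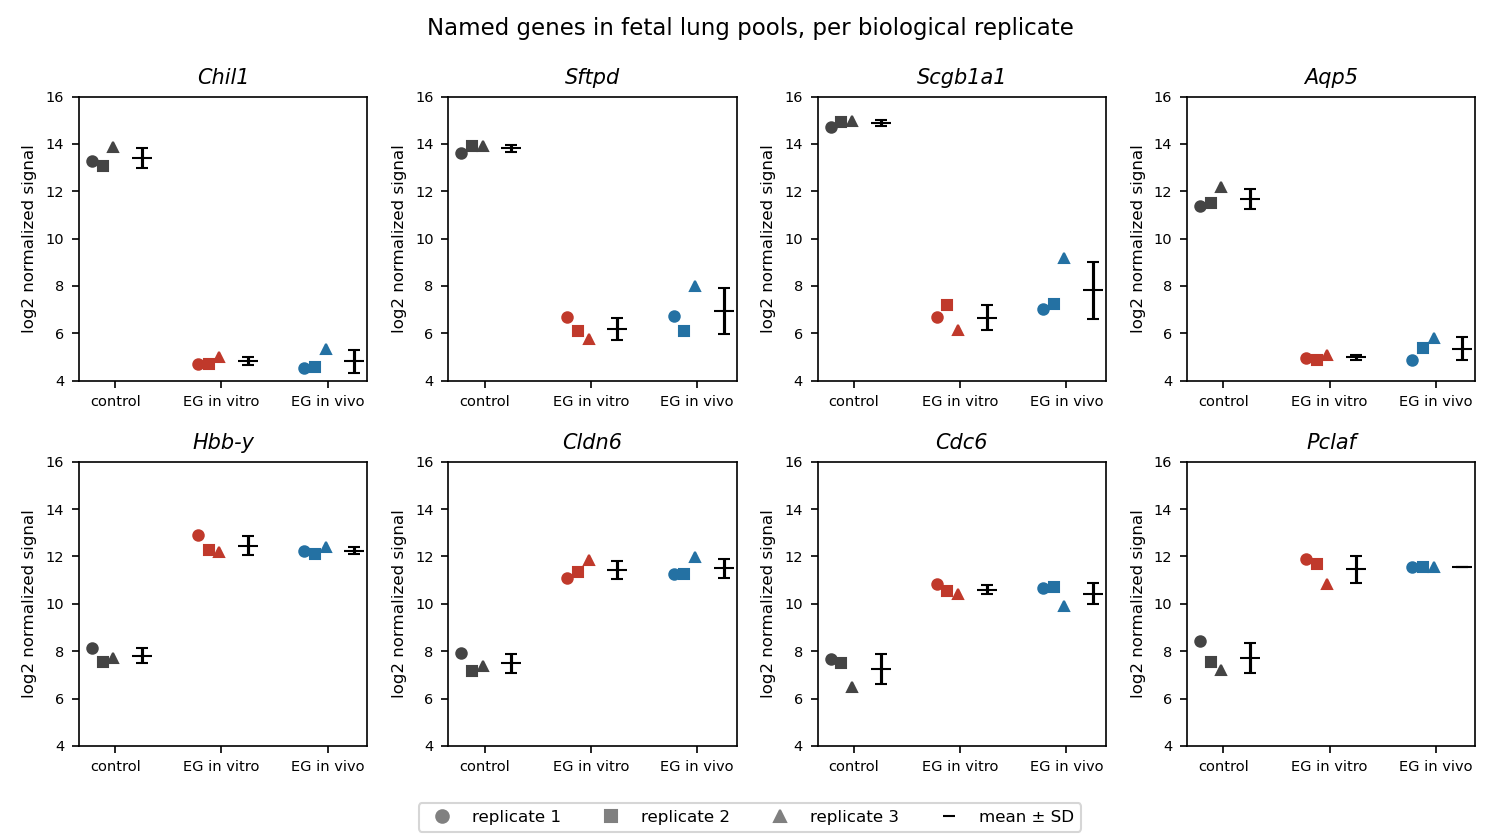
Normalized log2 signal of 8 named genes in each pool (symbols mark replicate numbers), with the mean and SD of the 3 pools beside them. Chil1, Sftpd, Scgb1a1 and Aqp5 were higher in every control pool than in any pool of the transfer groups, and Hbb-y, Cldn6, Cdc6 and Pclaf were lower in every control pool.

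The alveolar, club cell and ciliated cell lists fell in EG in vitro. Of 22 measured alveolar type II and surfactant genes, 18 fell and 0 rose (19 and 0 adjusted over the list alone), with a median of -2.60, or -2.55 with undetected genes at their bound (camera adjusted p = 6.41e-10, adjusted p = 0.0600 with an estimated correlation). Besides Chil1 and Sftpd they included Sftpa1, surfactant protein A (-5.27), and Hc, complement component C5 (-4.93). Of 16 alveolar type I genes, 15 fell and 1 rose (15 and 1 adjusted over the list alone), with a median of -2.47 (camera adjusted p = 2.99e-08, adjusted p = 0.0698 with an estimated correlation). Examples were Sec14l3, a lipid-binding protein (-4.46), Clic5, a chloride intracellular channel protein (-3.66), and Ager, the receptor RAGE (-3.09). Of 10 club cell genes, 9 fell (9 adjusted over the list alone), with a median of -3.88, or -3.59 at the bound (camera adjusted p = 1.46e-05, adjusted p = 0.0802 with an estimated correlation), among them Cbr2, a carbonyl reductase (-5.64), Hp, haptoglobin (-4.64), and Cyp2f2, a cytochrome P450 (-4.14). Of 17 ciliated cell genes, 16 fell (17 adjusted over the list alone), with a median of -1.98 (camera adjusted p = 9.18e-09, adjusted p = 0.0972 with an estimated correlation), including Cdhr3 (-4.16), Dnali1, a dynein chain (-2.95), Fam183b (-2.92) and Sntn, sentan of cilia tips, at least 10.1-fold lower.

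Genes that respond to glucocorticoids and genes of ion and water transport fell too. In the glucocorticoid response list 20 of 27 genes fell and 1 rose (20 and 1 adjusted over the list alone), with a median of -1.20 (camera adjusted p = 9.58e-08, adjusted p = 0.0541 with an estimated correlation). Besides Lcn2 these included Scnn1a, the alpha subunit of the epithelial sodium channel (-4.62), Sult1a1, a sulfotransferase (-4.12), and Hsd11b1, which regenerates active glucocorticoid (-3.38). In the ion and fluid transport list 12 of 16 fell and 2 rose (12 and 2 adjusted over the list alone), with a median of -1.50 (camera adjusted p = 6.23e-05, adjusted p = 0.104 with an estimated correlation). The other sodium channel subunits Scnn1g and Scnn1b changed by -3.03 and -2.83.

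Cell cycle genes moved the other way. Of 40 measured genes 35 rose and 0 fell (35 and 0 adjusted over the list alone), with a median of 2.39 (camera adjusted p = 3.60e-18, adjusted p = 0.0698 with an estimated correlation). Examples were Cdc6, which loads replication origins (3.37), the kinases Melk (2.90) and Aurkb (2.90), and Mcm5 of the replicative helicase (2.84). In the DNA methylation and chromatin list 14 of 20 rose and 0 fell (15 and 0 adjusted over the list alone), with a median of 0.64 (camera adjusted p = 5.07e-05, adjusted p = 0.0541 with an estimated correlation). Those with the largest change act on replicating DNA or silence genes: Uhrf1 (2.87) and the methyltransferases Dnmt1 (1.91) and Ezh2 (1.52). In the oxidative phosphorylation list 14 of 50 rose and 0 fell (12 and 0 adjusted over the list alone), with a median of 0.34 (camera adjusted p = 0.00119, adjusted p = 0.0972 with an estimated correlation), among them Cycs, cytochrome c (0.85), and Ndufa5 of complex I (0.81).

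Immune genes were lower in EG in vitro lungs. Of 26 interferon response genes 24 fell and 0 rose (25 and 0 adjusted over the list alone), with a median of -1.59 (camera adjusted p = 3.65e-09, adjusted p = 0.104 with an estimated correlation). They included the antiviral genes Rsad2 (-3.62) and Oasl2 (-3.11), Usp18 (-2.96), which removes ISG15 from proteins, and the transcription factor Irf7, at least 4.40-fold lower. Of 12 granulocyte genes 11 fell (11 adjusted over the list alone), with a median of -2.48, or -2.22 at the bound (camera adjusted p = 1.98e-06, adjusted p = 0.0600 with an estimated correlation), including S100a9 (-3.65), Chil3 (at least 13.2-fold lower) and Retnlg (at least 7.25-fold lower). Of 18 macrophage and monocyte genes 12 fell and 0 rose (15 and 0 adjusted over the list alone), with a median of -0.89 (camera adjusted p = 5.19e-05, adjusted p = 0.0698 with an estimated correlation), including Lyz1, a lysozyme (-3.77, from a control level of 14.93 that is also close to the top), Mpeg1 (-2.41) and Tyrobp (-1.49).

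Vessel and covering layers of the lung showed lower marker levels. Of 27 endothelium genes 17 fell and 1 rose (19 and 1 adjusted over the list alone), with a median of -0.88 (camera adjusted p = 3.44e-05, adjusted p = 0.0758 with an estimated correlation), including Gpihbp1, which anchors lipoprotein lipase on capillaries (-2.49), and Vwf (-1.89). Of 6 mesothelium genes 4 fell (5 adjusted over the list alone), with a median of -1.26 (camera adjusted p = 0.00914, adjusted p = 0.0802 with an estimated correlation), led by Msln, mesothelin (-5.25). Genes of heart muscle can also come from neighbouring tissue. Of 12 heart muscle genes 11 fell (11 adjusted over the list alone), with a median of -1.65 (camera adjusted p = 0.000404, adjusted p = 0.259 with an estimated correlation). Ryr2, the cardiac calcium release channel, changed by -2.42 and Myh6, a cardiac myosin, by -2.04. In the mesenchyme and fibroblast list 13 of 26 fell and 3 rose (13 and 3 adjusted over the list alone), with a median of -0.51 (camera adjusted p = 0.0306, adjusted p = 0.109 with an estimated correlation). Fn1, fibronectin, changed by -2.36 and Lum, lumican, by 2.86. That list was not past the threshold with the replicate number as a block (adjusted p = 0.0761), with bright or dim arrays as a block (adjusted p = 0.0752), without control replicate 3 (median -0.39, adjusted p = 0.0566) or with replicates 1 and 2 only (median -0.47, adjusted p = 0.102).

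Clock and immediate early genes were mostly lower in EG in vitro, and hypoxia genes went both ways. In the circadian clock list 11 of 14 fell (11 adjusted over the list alone), with a median of -1.06 (camera adjusted p = 3.15e-05, adjusted p = 0.0541 with an estimated correlation), including the clock genes Rora (-1.75) and Per3 (-1.73), and Npas2 at least 2.80-fold lower. In the immediate early response list 15 of 24 fell and 3 rose (15 and 4 adjusted over the list alone), with a median of -0.95 (camera adjusted p = 0.00128, adjusted p = 0.0698 with an estimated correlation), including Ier3 (-2.76) and the AP-1 subunits Junb (-1.99) and Fos (-1.92). In the hypoxia response list 10 of 22 fell and 3 rose (11 and 4 adjusted over the list alone), with a median of -0.55 (camera adjusted p = 0.0225, adjusted p = 0.373 with an estimated correlation). Adm, adrenomedullin, changed by -2.50 and Vegfa, the vascular growth factor, by -1.54. The hypoxia list was past the threshold neither under median scaling (adjusted p = 0.0557) nor without control replicate 1 (median -0.40, adjusted p = 0.0628). The antioxidant and redox list, a property named in the study's design, held 15 lower and 6 higher of 39 genes (15 and 7 adjusted over the list alone) and did not pass camera as a list (median -0.28, adjusted p = 0.1003), but passed fry (adjusted p = 0.000296). Those named by the rule were Xdh, xanthine dehydrogenase (-3.95), Gpx3, a secreted glutathione peroxidase (-3.18), Gstm1, a glutathione transferase (-2.21), and Aldh3a1, detected on 1 EG in vitro array and at least 6.59-fold lower.

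**Figure D3:**
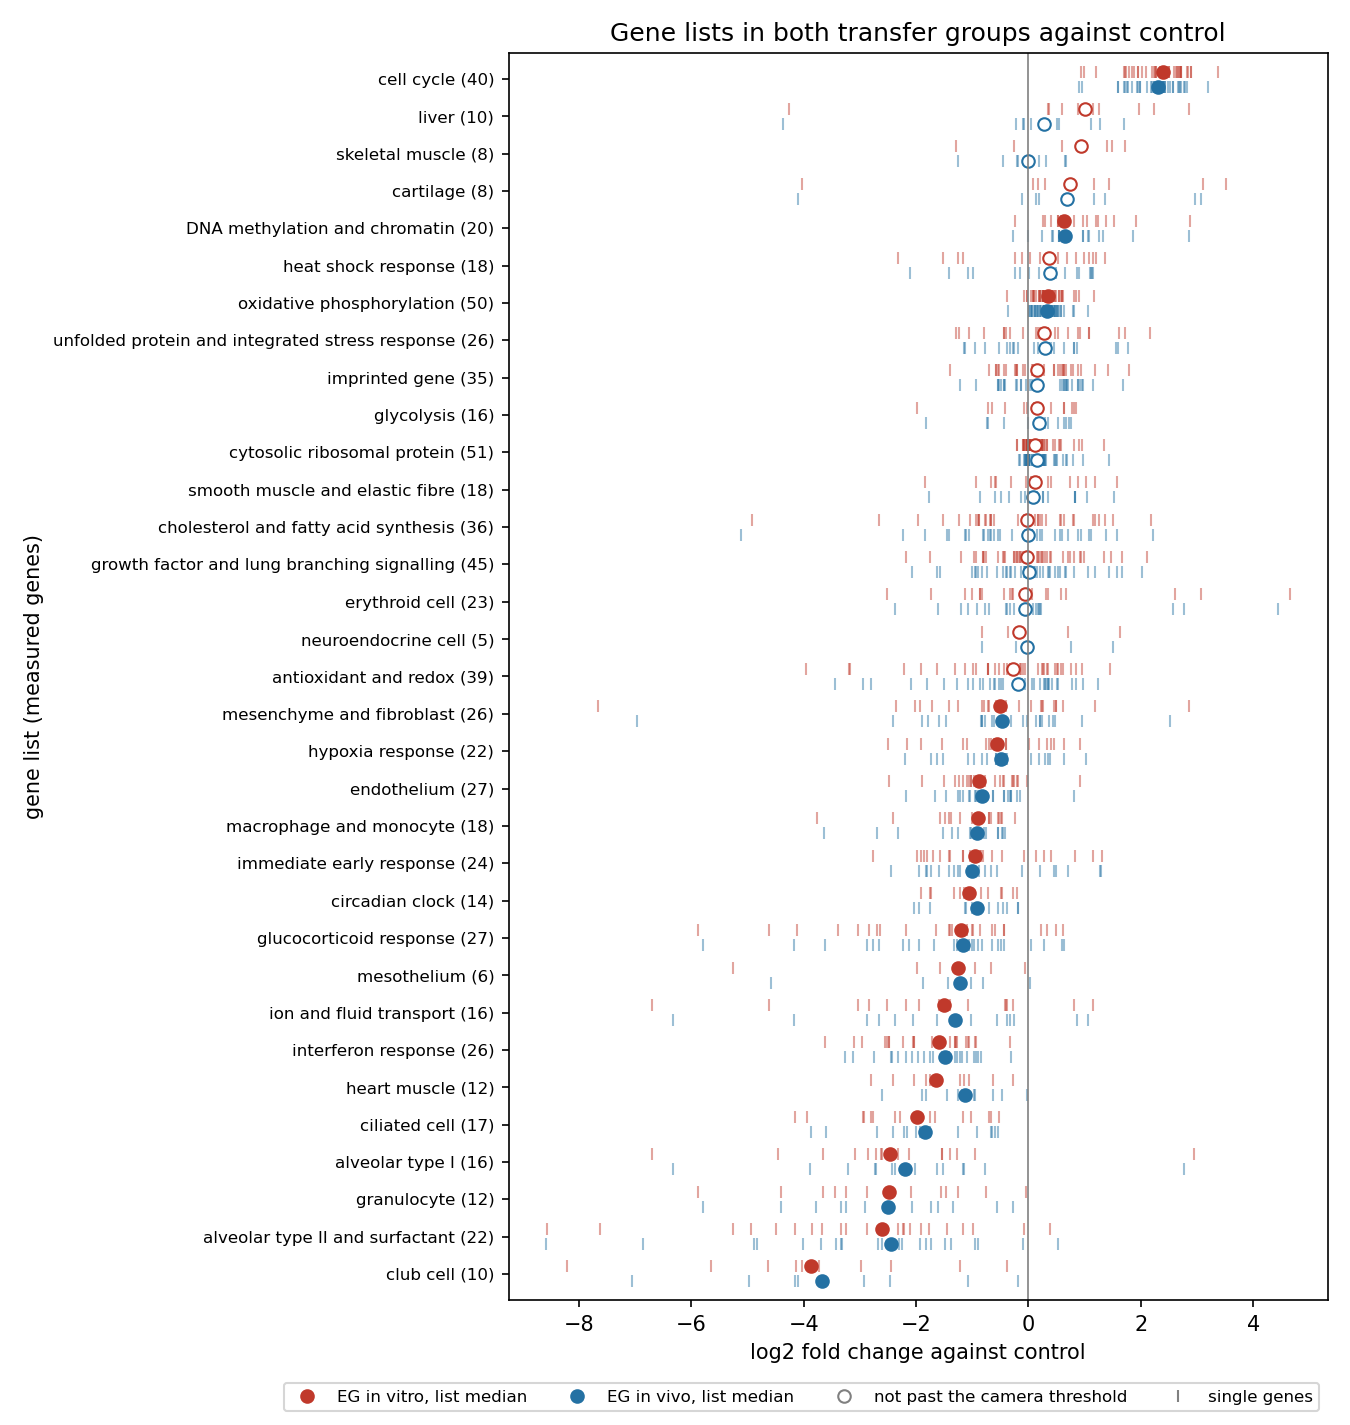
Log2 fold change against control for the measured genes of each tested list (ticks) with the list median (circles), in EG in vitro and EG in vivo, with undetected genes at their fitted value. Filled circles mark lists past the camera threshold at the preset correlation, 19 in each comparison, and 0 passed with an estimated correlation. The cell cycle list lies highest in both, at medians of 2.39 and 2.31.

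The comparison of EG in vivo with control carries transfer of blastocysts that had not been derived in vitro. Here too surfactant, airway and alveolar genes were far lower and proliferation genes and embryonic globins higher. Scgb1a1 fell by 7.05 ± 0.53 from the same high control level (SE, n = 3 pools per group, adjusted p = 2.92e-05) and Sftpd by 6.86 ± 0.44 (adjusted p = 1.56e-05). Aqp5, detected on 3 of 9 EG in vivo arrays, was at least 66.3-fold lower (adjusted p = 3.93e-06), and Chil1, detected on 2 of 9, at least 263-fold lower (adjusted p = 2.14e-06). Hbb-y rose by 4.44 ± 0.23 (adjusted p = 6.27e-06) and Cldn6 by 4.02 ± 0.29 (adjusted p = 2.30e-05).

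In EG in vivo 4664 probes rose and 4347 fell, 39.2% of those tested, with 1785 higher and 2151 lower at least 2-fold. All 3 pools of 1 group lay above the other 3 for 48.6% of probes, where chance gives 10%. The total of 9011 became 15719 with array weights, 14547 with arrays taken as independent and 5756 when a change beyond 1.2-fold was tested. The other lowest genes were Pon1 (at least 87.2-fold lower), Inmt (-6.97 ± 0.33), Chia1 (-5.80 ± 0.31), Car4 (at least 37.0-fold lower, detected on 1 array), Lcn2 (at least 37.2-fold lower, detected on 1 array) and Gjb6 (at least 33.1-fold lower, detected on 2 arrays). The other highest were Lin7a (at least 15.2-fold higher), Pclaf (3.83 ± 0.35), Septin3 (at least 12.3-fold higher), Cfi (3.54 ± 0.12), Dctd (3.25 ± 0.17), Mcm10, a replication initiation factor (3.29 ± 0.16), Cenph of the kinetochore (3.22 ± 0.32), and Adamts18 (at least 9.89-fold higher). All of these kept their call and direction in every alternative fit.

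These lists fell in EG in vivo as well. Alveolar type II and surfactant genes had 18 of 22 lower and 0 higher (19 and 0 adjusted over the list alone), with a median of -2.45, or -2.42 at the bound (camera adjusted p = 5.37e-10, adjusted p = 0.0532 with an estimated correlation), including Hc (-4.88) and Sftpa1 (-4.83). Alveolar type I genes had 15 of 16 lower and 1 higher (15 and 1 adjusted over the list alone), with a median of -2.20 (camera adjusted p = 2.27e-08, adjusted p = 0.0642 with an estimated correlation). The exception was Igfbp2, an IGF binding protein (2.77). Club cell genes had 9 of 10 lower (9 adjusted over the list alone), with a median of -3.68, or -3.35 at the bound (camera adjusted p = 1.21e-05, adjusted p = 0.0793 with an estimated correlation), including Cbr2 (-4.97). Ciliated cell genes had 16 of 17 lower (17 adjusted over the list alone), with a median of -1.83 (camera adjusted p = 1.91e-08, adjusted p = 0.0924 with an estimated correlation), including Cdhr3 (-3.60) and Sntn (at least 9.36-fold lower). Glucocorticoid response genes had 20 of 27 lower and 0 higher (20 and 2 adjusted over the list alone), with a median of -1.16 (camera adjusted p = 5.82e-08, adjusted p = 0.0532 with an estimated correlation), including Scnn1a (-4.17). Ion and fluid transport genes had 12 of 16 lower and 2 higher (13 and 2 adjusted over the list alone), with a median of -1.31 (camera adjusted p = 4.75e-05, adjusted p = 0.0924 with an estimated correlation), including Scnn1g (-2.87).

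Proliferation lists rose and immune lists fell in EG in vivo. In the cell cycle list 35 of 40 rose and 0 fell (35 and 0 adjusted over the list alone), with a median of 2.31 (camera adjusted p = 5.63e-18, adjusted p = 0.0642 with an estimated correlation), led by Cdc6 (3.19). In the DNA methylation and chromatin list 14 of 20 rose and 0 fell (15 and 1 adjusted over the list alone), with a median of 0.64 (camera adjusted p = 0.000165, adjusted p = 0.0532 with an estimated correlation), including Uhrf1 (2.86), Dnmt1 (1.87) and Dnmt3l, a cofactor of de novo methylation, detected on 1 control array and at least 2.13-fold higher. In the oxidative phosphorylation list 13 of 50 rose and 0 fell (13 and 0 adjusted over the list alone), with a median of 0.33 (camera adjusted p = 0.00129, adjusted p = 0.0924 with an estimated correlation). Interferon response genes had 23 of 26 lower and 0 higher (25 and 0 adjusted over the list alone), with a median of -1.48 (camera adjusted p = 2.29e-09, adjusted p = 0.0939 with an estimated correlation), including Rsad2 (-3.26) and H2-D1, a class I histocompatibility antigen (-2.45). Granulocyte genes had 10 of 12 lower (10 adjusted over the list alone), with a median of -2.49, or -2.25 at the bound (camera adjusted p = 3.38e-07, adjusted p = 0.0532 with an estimated correlation), including S100a9 (-3.78). Macrophage and monocyte genes had 13 of 18 lower and 0 higher (15 and 0 adjusted over the list alone), with a median of -0.92 (camera adjusted p = 1.21e-05, adjusted p = 0.0532 with an estimated correlation), including Lyz1 (-3.64, from the same high control level).

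The remaining lists past the threshold were lower in EG in vivo. Endothelium genes had 18 of 27 lower and 1 higher (18 and 1 adjusted over the list alone), with a median of -0.82 (camera adjusted p = 1.21e-05, adjusted p = 0.0642 with an estimated correlation), including Gpihbp1 (-2.19). Mesothelium genes had 5 of 6 lower (5 adjusted over the list alone), with a median of -1.22 (camera adjusted p = 0.00649, adjusted p = 0.0713 with an estimated correlation), led by Msln (-4.58). Heart muscle genes had 7 of 12 lower (10 adjusted over the list alone), with a median of -1.13 (camera adjusted p = 0.00193, adjusted p = 0.339 with an estimated correlation), including Ryr2 (-1.89). Circadian clock genes had 11 of 14 lower (11 adjusted over the list alone), with a median of -0.92 (camera adjusted p = 3.10e-05, adjusted p = 0.0532 with an estimated correlation), including Per3 (-2.04). Immediate early response genes had 15 of 24 lower and 3 higher (15 and 5 adjusted over the list alone), with a median of -1.001 (camera adjusted p = 0.00109, adjusted p = 0.0642 with an estimated correlation), including Ier3 (-2.45). Mesenchyme and fibroblast genes had 11 of 26 lower and 3 higher (12 and 3 adjusted over the list alone), with a median of -0.47 (camera adjusted p = 0.0186, adjusted p = 0.0924 with an estimated correlation), including Fn1 (-2.41), and did not pass with replicates 1 and 2 only (median -0.46, adjusted p = 0.0730). Hypoxia response genes had 9 of 22 lower and 2 higher (9 and 4 adjusted over the list alone), with a median of -0.48, or -0.43 at the bound (camera adjusted p = 0.0237, adjusted p = 0.393 with an estimated correlation), including Adm (-2.20). The hypoxia list did not pass under median scaling (adjusted p = 0.0689) or without control replicate 1 (median -0.31, adjusted p = 0.0739). The antioxidant and redox list had 15 of 39 genes lower and 6 higher (15 and 7 adjusted over the list alone) and did not pass camera (median -0.18, adjusted p = 0.0764) but passed fry (adjusted p = 0.000755), with Xdh at -3.44 and Gpx3 at -2.81.

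Both transfer groups departed from the controls in the same direction at the genes above. Across 22958 probes the changes correlated at 0.982, where probes are not independent replicates and unchanged groups simulated 100 times against the same controls gave 0.499. The covariance was 0.798 against 0.0515 simulated. Both comparisons called 4229 probes higher, where independent lists of these sizes would share 961, and 4043 lower, where they would share 864, and 0 probes passed in opposite directions. The simulated groups shared the controls as well, with a highest covariance of 0.0566, so noise between control pools gives little of this excess. A deviation common to all 3 control pools would not show in the simulation. The controls could not be split into 2 sets of at least 2 pools, so a part from such a deviation stays open. The slope of the EG in vivo change on the EG in vitro change was 0.932.

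**Figure D4:**
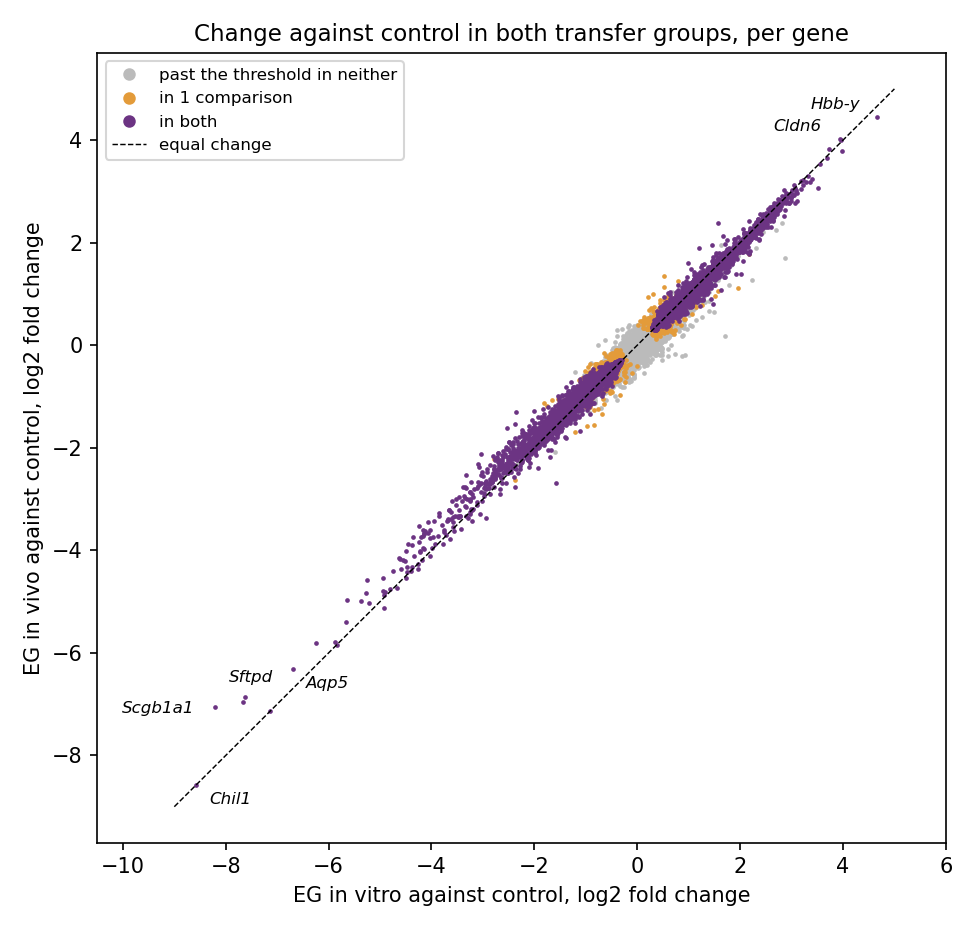
Log2 fold change against control of each gene in EG in vitro (horizontal) and EG in vivo (vertical), coloured by whether it passed the threshold in both, 1 or neither comparison. The dashed line marks equal change. Chil1, Scgb1a1, Sftpd and Aqp5 lie at the low end and Hbb-y and Cldn6 at the high end, and 0 probes passed in opposite directions.

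The comparison of EG in vitro with EG in vivo carries derivation of the blastocyst in vitro, since both groups had a transfer. Ciliated cell and alveolar genes lay slightly lower in EG in vitro as lists, with smaller medians once EG in vivo replicate 3 was left out. These lists passed neither with an estimated correlation (adjusted p = 0.320 for each) nor in fry (adjusted p = 0.687 for each), and no gene passed singly. Scgb1a1 differed by -1.15 ± 0.53 (SE, n = 3 pools per group) and Sftpd by -0.76 ± 0.44, both with adjusted p = 0.999914. Within EG in vivo, replicate 3 stood highest for both. It lay at 9.19 against 7.01 and 7.24 for Scgb1a1 and at 7.998 against 6.73 and 6.11 for Sftpd. Of 17 ciliated cell genes 15 were lower in EG in vitro, with a median difference of -0.26 (camera adjusted p = 1.54e-06, adjusted p = 0.320 with an estimated correlation). Most of that difference lay in EG in vivo replicate 3, where the list stood at -0.09 relative to the mean of all pools against -0.79 and -0.69 in the other pools of its group. Without that pool the median difference was -0.089 (adjusted p = 0.0143), and with replicates 1 and 2 only it was -0.034 and did not pass (adjusted p = 0.191). The skeletal muscle list had a median difference of 0.77, carried by EG in vitro replicate 3, and the liver list 0.69, carried by EG in vitro replicate 1. Both had 0 members past the threshold and no call with an estimated correlation (adjusted p = 0.416 and 0.410) or in fry (adjusted p = 0.708 for both).

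limma called 0 of 22958 probes, with 285 at an unadjusted p under 0.05, where chance gives 1148 if pools are independent. The random block called 1 probe, array weights 2, arrays taken as independent 122 and every other setting 0. The 3 pools of 1 group lay above the other 3 for 5.34% of probes, where chance gives 10% for independent pools. The 95% confidence interval of the difference had a median width of ±0.43 on the log2 scale and lay within 2-fold either way for 87.3% of probes and within 1.5-fold for 54.5%. This fit leaves out that pools of 1 number deviated together, which adds to its error and lowers these counts. With the replicate number as a block 0 probes passed and 820 had an unadjusted p under 0.05, the median width was ±0.31, and the interval lay within 2-fold for 96.7% of probes. All 3 numbered pairs differed in the same direction for 23.7% of probes, where chance gives 25%. The lowest p among genes lower in EG in vitro belonged to Tgm1, a transglutaminase (at least 1.74-fold lower, detected on 5 EG in vitro arrays), Nuf2 of the kinetochore (-0.62 ± 0.11), Klhdc9 (-0.57 ± 0.13), Cyp3a13, a cytochrome P450 (-0.50 ± 0.12), and Enkur, a cilium protein (-0.58 ± 0.15). Those higher were Hpx, hemopexin (detected on 6 EG in vitro arrays and 0 EG in vivo arrays, too dim for a fold), Ptn, the growth factor pleiotrophin (0.37 ± 0.13), Uap1 (0.40 ± 0.14), Lrfn2 (at least 1.07-fold higher, detected on 3 EG in vivo arrays) and Mgl2, a macrophage lectin (0.49 ± 0.17). None of these passed (adjusted p = 0.999914).

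Of 33 lists 9 passed camera in this comparison, 0 with an estimated correlation and 0 in fry, and 0 members passed over all probes. Adjusted over each list alone, 1 cell cycle gene, Nuf2, passed as lower, and no member of another list did. Alveolar type II and surfactant genes were lower by a median of -0.24 (camera adjusted p = 8.06e-05, adjusted p = 0.320 with an estimated correlation), but not past the threshold without EG in vitro replicate 3 (median -0.19, adjusted p = 0.176) or with replicates 1 and 2 only (median -0.055, adjusted p = 0.441). Alveolar type I genes were lower by -0.23 (camera adjusted p = 0.000153, adjusted p = 0.320 with an estimated correlation), including Hopx (-0.45 ± 0.16). That list stood at -0.40 relative to the mean of all pools in EG in vivo replicate 3, against -0.80 in both other pools of the group and -0.89 to -0.76 in EG in vitro, and did not pass with replicates 1 and 2 only (median -0.10, adjusted p = 0.0838). Glucocorticoid response genes were lower by -0.14 (camera adjusted p = 0.00178, adjusted p = 0.320 with an estimated correlation), though not without EG in vitro replicate 3 (median -0.15, adjusted p = 0.0731). Heart muscle genes were lower by -0.36 (camera adjusted p = 0.000316, adjusted p = 0.419 with an estimated correlation), though not without EG in vivo replicate 2 (median -0.27, adjusted p = 0.299). Skeletal muscle genes, with Acta1, skeletal actin, at 1.53 ± 0.88 (camera adjusted p = 2.34e-05, adjusted p = 0.416 with an estimated correlation), had a median of 0.07 and adjusted p = 0.513 without EG in vitro replicate 3. Liver genes, with Afp, alpha-fetoprotein, at 1.17 ± 1.18 (camera adjusted p = 2.56e-06, adjusted p = 0.410 with an estimated correlation), had a median of 0.08 and adjusted p = 0.615 without EG in vitro replicate 1. The median of the liver list relative to the mean of all pools was 1.92 in EG in vitro replicate 1 and between -0.59 and 0.57 in the other 8 pools, and that of the skeletal muscle list 2.15 in EG in vitro replicate 3 and between -0.69 and 0.10 in the others.

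Cartilage genes differed by a median of 0.10 (camera adjusted p = 0.0343, adjusted p = 0.320 with an estimated correlation), with Col2a1 at 0.43 ± 0.35. Their median was 0.14 without EG in vitro replicate 1 (adjusted p = 0.110), 0.035 without EG in vitro replicate 3 (adjusted p = 0.314) and 0.10 without EG in vivo replicate 3 (adjusted p = 0.856). With replicates 1 and 2 only it was -0.041 (adjusted p = 0.975). The cartilage list also did not pass without background correction (median 0.040, adjusted p = 0.0795) or with the authors' values (median 0.043, adjusted p = 0.0761). DNA methylation and chromatin genes differed by 0.021 (camera adjusted p = 0.0499, adjusted p = 0.320 with an estimated correlation), with Ezh2 at 0.55 ± 0.34. Their median was 0.018 without EG in vitro replicate 1 (adjusted p = 0.249) and 0.019 without EG in vitro replicate 3 (adjusted p = 0.176). It was 0.017 without EG in vivo replicate 2 (adjusted p = 0.177), 0.026 without EG in vivo replicate 3 (adjusted p = 0.401) and -0.02 under median scaling (adjusted p = 0.198). With replicates 1 and 2 only, 4 lists passed: liver (median 1.03, adjusted p = 5.18e-06), heart muscle (-0.37, adjusted p = 0.00254), glucocorticoid response (-0.092, adjusted p = 0.0218) and erythroid cell (0.057, adjusted p = 0.0392), the last of which did not pass with all pools. With an estimated correlation 0 lists passed in these pools (adjusted p = 0.944 for each of the 4). These pools include EG in vitro replicate 1, which carried the liver list. With the replicate number as a block all 9 remained, and the cell cycle (median 0.05, adjusted p = 0.00637), ion and fluid transport (-0.14, adjusted p = 0.0373) and club cell lists (-0.16, adjusted p = 0.0463) passed in addition. In that fit 0 lists passed with an estimated correlation, at adjusted p = 0.705 for the cell cycle list and 0.532 for the ion and fluid transport and club cell lists. With members detected on fewer than 6 arrays of a group at their bound, the median difference was 0.46 for liver, -0.26 for heart muscle and 0.0037 for cartilage genes. Without the block the 24 lists that did not pass had adjusted p between 0.0541 and 0.993.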

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

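The fits without replicate 3, the values per pool and the tests of signal compression and of stage in replicate 3 were chosen after the results had been seen.

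Lists of differentiated epithelium lay lower in EG in vitro than in EG in vivo, and each was noted because the difference between the transfer groups was tested itself. The median differences were -0.26 for ciliated cell genes, -0.24 for alveolar type II and surfactant genes, -0.23 for alveolar type I genes and -0.14 for glucocorticoid response genes. Heart muscle genes differed by -0.36, liver genes by 0.69, skeletal muscle genes by 0.77, cartilage genes by 0.10 and DNA methylation and chromatin genes by 0.021. None of the 9 passed with an estimated correlation. With replicates 1 and 2 only the ciliated cell, alveolar type II and alveolar type I lists lost their call, at medians of -0.034, -0.055 and -0.10 (adjusted p = 0.191, 0.441 and 0.0838). In EG in vivo replicate 3 the ciliated cell list stood at -0.09 relative to the mean of all pools, against -0.79 and -0.69 in EG in vivo replicates 1 and 2 and -0.92 to -0.71 in EG in vitro. Its club cell list stood at -0.52 against -1.43 and -1.27 in the other EG in vivo pools, and its interferon response list at 0.06 against -0.67 and -0.64.

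An array of the same pool detected fewer probes than the other 8 arrays of its group. Technical array 3 of EG in vivo replicate 3 detected 19762 probes, and the next lowest of the group 21173. It was the 1 extreme among 12 that lay beyond Dixon's 95% critical value, where chance gives about 1 in 20 for independent values. The 9 arrays of a group are technical arrays of 3 pools, so that rate does not hold strictly here.

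Replicate 3 stood apart from replicates 1 and 2 in all groups and its arrays were dimmer. The change against control in replicate 3 was set against that in replicates 1 and 2 after quantile normalization. Its slope was 1.03 in EG in vitro and 0.936 in EG in vivo, so little compression of differences remained in those values. Normalization gives all arrays the same distribution, so the slopes cannot tell whether the dim arrays compressed the raw signals. A batch of arrays or hybridisations may contribute. Different probes of 1 gene shared the deviation of replicate 3 with correlations across 4908 genes of 0.235 in controls, 0.199 in EG in vitro and 0.350 in EG in vivo. Noise at single probes would lower such correlations under any cause. No level expected from noise was set beside them, so they cannot decide whether a batch contributed. A difference in fetal stage stays open. The deviation correlated with the change of the other transfer group against control at -0.0369 in EG in vitro and -0.202 in EG in vivo. In controls, replicate 3 minus replicate 1 correlated at 0.111 with the mean of the transfer pools minus control replicate 2. That mean includes replicate 3 of the transfer groups, so its sign cannot be set against the others. No group of the design follows the replicate number, so no biological explanation from the design was tested.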

How the results depend on the processing

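The fits of replicates 1 and 2 only and of bright or dim arrays as a block were chosen after the data had been seen, and all other alternatives were planned. Signal over background limits genes near the detection limit, whose fold changes depend on the offset and are given as bounds where a group detected them on fewer than 6 arrays. Probes called in EG in vitro against control numbered 9292, and 14788 with arrays as independent, 17937 with array weights, 6146 with treat and 5608 with 1 probe per gene. In EG in vivo against control they numbered 9011, and 14547, 15719, 5756 and 5433 in these settings. Treating arrays as independent counts technical arrays as replicates, treat asks for a change beyond 1.2-fold and 1 probe per gene tests fewer features. The estimation of array weights did not converge, and the cause of its counts was not tested. With the replicate number as a block the totals were 12799, 12471 and 0, and on leaving out 1 pool 7286 to 10132, 7234 to 8927 and 0 to 0. With replicates 1 and 2 only they were 12360, 11967 and 0, and with the bright or dim block 13245, 12869 and 0. No probe called in the main fit changed direction in another setting that called it, and the share of higher calls stayed between 47.7% and 54.2%. Between the transfer groups the count of 0 became 1 with the random block, 122 with arrays as independent and 2 with array weights.

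The counts of lists past camera were 19, 19 and 9. An estimated correlation gave 0 in each comparison. Leaving out 1 pool gave 18 to 19, 18 to 19 and 4 to 13, with 4 without EG in vitro replicate 3 between the transfer groups. Replicates 1 and 2 only gave 4 there, and the cause was not tested. fry, which asks whether a list changed at all and not whether it changed more than other genes, gave 25, 25 and 0, with the 19 of camera and 6 more in each comparison with controls. The replicate block changed no list call beyond those given in the report. Between the transfer groups the interferon response list, at a median of -0.08, was not past the threshold (camera adjusted p = 0.299, adjusted p = 0.873 with an estimated correlation). On leaving out 1 pool its medians lay between -0.23 (without EG in vivo replicate 1) and 0.085. At the latter, without EG in vivo replicate 3, it passed camera as higher at the preset correlation (adjusted p = 0.0293). No value with an estimated correlation is given for that fit. The correlation of both changes against control lay between 0.956 and 0.983 on leaving out 1 pool, with 0.956 without EG in vitro replicate 3, 0.964 without EG in vivo replicate 1 and 0.960 without EG in vivo replicate 2. The ratio of the spread between pool means to that between single technical arrays was 1.73, 1.75 without background correction and 1.74 from the authors' values.

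Of 10611 checks of named genes 10453 kept direction and side of the threshold, 143 lost the call, 15 gained it and 0 reversed. Of 1782 checks of lists 1662 kept both, 88 lost the call, 31 gained it and 1 reversed. The kept checks include 110 of genes and 72 of lists that were not called and changed sign. No other scaling moved the median of all probes by over 0.1. A slide block was not run, since no slide is named in the sources used here.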

Other observations

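The test of Xist and the look at globin levels were chosen after the results had been seen, and the other tests below were set before theirs.

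Embryonic globins rose in both transfer groups against controls. Besides Hbb-y, Hba-x rose by 3.08 ± 0.31 in EG in vitro and 2.77 ± 0.31 in EG in vivo (SE, n = 3 pools per group), and Hbb-bh1, detected on 2 control arrays, was at least 4.82- and 4.70-fold higher. The adult globin Hba-a1 stood at 14.80, 14.74 and 14.75 in controls, EG in vitro and EG in vivo, close to the top of the arrays' range, where a change may be hidden. Hbb-b2, another adult globin, stood lower, at 12.61, 12.31 and 12.28, and did not pass (-0.29 and -0.33, adjusted p = 0.391 and 0.344). In the erythroid cell list 3 of 23 rose and 6 fell in each comparison (3 and 6 adjusted over the list alone), and it did not pass (medians -0.06 and -0.07, camera adjusted p = 0.484 and 0.357). Aqp1, a water channel of red cells and vessels, changed by -2.52 and -2.38. In the cartilage list, for a tissue of the large airways, 4 of 8 rose and 1 fell (4 and 1 adjusted over the list alone) in each comparison, with no call as a list (medians 0.74 and 0.68, or 0.70 and 0.61 at the bound, camera adjusted p = 0.134 and 0.286). Col9a1 changed by 3.10 and 2.96, and Chad, chondroadherin, detected on 2 EG in vitro and 3 EG in vivo arrays, was at least 14.4- and 13.1-fold lower. Every control pool lay below every pool of the transfer groups for Hbb-y and Col2a1.

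Genes of branching and metabolism went both ways. In the growth factor and lung branching signalling list 8 of 45 rose and 9 fell in EG in vitro and 6 and 8 in EG in vivo (the same counts adjusted over the list alone), with medians of -0.02 and 0.01 (camera adjusted p = 0.919 and 0.844). Etv4 and Sox9, transcription factors of growing lung tips, rose by 2.11 and 1.67 in EG in vitro and by 2.02 and 1.67 in EG in vivo, while Igfbp3, an IGF binding protein, changed by -2.17 and -2.08 and Hey1, a Notch target, by -1.75 and -1.62. In the cholesterol and fatty acid synthesis list 9 of 36 rose and 13 fell in EG in vitro and 9 and 12 in EG in vivo (the same counts adjusted over the list alone), with medians of -0.02 and -0.01 (camera adjusted p = 0.581 and 0.448). Scd1, a fatty acid desaturase, changed by -4.92 and -5.12 and the elongase Elovl6 by 2.19 and 2.21. In the unfolded protein and integrated stress response list 6 of 26 rose and 4 fell in EG in vitro and 5 and 5 in EG in vivo (the same counts adjusted over the list alone), with medians of 0.28 and 0.30 (camera adjusted p = 0.484 and 0.712). Of amino acid synthesis genes, Asns rose by 1.61 and 1.59, and Phgdh, detected on 4 control arrays, was at least 3.97- and 3.03-fold higher.

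The other lists did not pass camera against controls, though the imprinted gene and cytosolic ribosomal protein lists here, and the cartilage, cholesterol and unfolded protein lists above, passed fry in both comparisons. Heat shock response genes had 8 of 18 higher and 4 lower in EG in vitro and 7 and 4 in EG in vivo (8 and 4 adjusted over the list alone in each, medians 0.37 and 0.38, camera adjusted p = 0.474 and 0.490), with Cryab, a small heat shock protein, at -2.33 and -2.10. Cytosolic ribosomal protein genes had 8 of 51 higher in EG in vitro and 7 in EG in vivo, with 0 lower (3 and 5 higher adjusted over the list alone, medians 0.12 and 0.15, camera adjusted p = 0.103 and 0.0764), with Rps15a at 1.35 and 1.44. Imprinted genes had 10 of 35 higher and 6 lower in each (10 and 12 higher adjusted over the list alone, medians 0.15 and 0.15, camera adjusted p = 0.405 in both), with Dcn, decorin, at 1.18 and 0.95. Glycolysis genes had 3 of 16 higher in EG in vitro and 2 in EG in vivo, with 3 lower in each (the same counts adjusted over the list alone, medians 0.14 and 0.19, camera adjusted p = 0.643 in both), with Aldoc, an aldolase, at -1.97 and -1.83. Smooth muscle and elastic fibre genes had 6 of 18 higher and 4 lower in EG in vitro and 5 and 4 in EG in vivo (7 and 5 higher adjusted over the list alone, medians 0.11 and 0.09, camera adjusted p = 0.671 and 0.749), with Eln, elastin, at -1.85 and -1.76 and Actg2, a smooth muscle actin, at 1.57 and 1.51. Neuroendocrine cell genes had 2 of 5 higher and 1 lower in each (the same counts adjusted over the list alone, medians -0.17 and -0.02, camera adjusted p = 0.791 and 0.749), with Uchl1, a neuronal ubiquitin hydrolase, at 1.62 and 1.501. Liver genes had 1 of 10 higher and 1 lower in EG in vitro and 0 and 1 in EG in vivo (0 and 1 adjusted over the list alone in each, medians 1.01 and 0.27, or 0.82 and 0.08 at the bound, camera adjusted p = 0.425 and 0.926), with Trf, transferrin, at -4.26 and -4.36. Skeletal muscle genes had 1 of 8 lower in each (1 adjusted over the list alone, medians 0.94 and -0.0030, camera adjusted p = 0.553 and 0.749). The EG in vitro medians of both lists rest on 1 pool each: relative to the mean of all pools the liver list stood at 1.92 in EG in vitro replicate 1 against 0.29 and -0.32 in the others of its group, and the skeletal muscle list at 2.15 in replicate 3 against 0.10 and -0.60. In 15 of 99 list tests, 0 of them past the threshold, the median, the mean and the test's direction differed in sign, among them the erythroid, neuroendocrine and growth factor lists against controls.

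Both transfer groups departed from controls. An array or hybridisation batch of the control arrays, as the only cause, is argued against by the agreement of different probes of 1 gene. Their changes correlated at 0.882 in EG in vitro and 0.867 in EG in vivo over 4908 genes. A batch shift added to larger changes would leave these correlations high, so a contribution of a batch stays open. A difference in dissection, RNA or collection would pass this test and stays open too. Tissue from outside the lung that lacks vessels and fibroblasts would, on diluting the transferred lungs, lower lung lists alike. Yet endothelium and mesenchyme medians lay 1.63 to 2.09 above the alveolar type II median, with the lowest 95% bootstrap bound over genes at 0.923. That gap argues against such dilution as the only cause, and not against dilution beside a separate fall of alveolar genes. Tissue with vessels or fibroblasts of its own would pass this test and stays open. An earlier developmental stage of the transferred fetuses at collection may account for the pattern. The 14 genes taken here to decline with fetal growth, with members of the cell cycle list left out, had medians of 0.648 (95% bootstrap interval over genes 0.454 to 1.03) and 0.730 (0.164 to 0.945). Of these 8 were higher and 0 lower in EG in vitro and 7 and 1 in EG in vivo, led by Ezh2 (1.52) in EG in vitro and by Sox11 (1.14) in EG in vivo. Ezh2 also stands in the DNA methylation and chromatin list, so the set is not independent of the lists above and cannot tell stage from cell division. Both bootstraps resampled genes with the pools held fixed, so they do not measure the spread between pools. An effect of the transfer itself, which the design names, was not tested apart from stage and stays open. The labels do not say whether days of gestation were counted alike in controls and transfer groups, so the stage named may not be the same age, and the comparisons with controls may carry a difference in age beside the transfer.

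Other splits of the pools were fitted as well. The 6 pools of each comparison form 10 splits, too few for a share under 0.05. The real split gave 9292 calls in EG in vitro against control and 9011 in EG in vivo against control, with 1 of 10 splits as large and a highest other count of 0 in each. Between the transfer groups the real split gave 0 and all 10 gave at least as many, with 1 as the highest other. Of the 4 splits that part all 3 numbered pairs, the real split included, the highest other count was 0 in each comparison.

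Xist in control replicate 1 departed from the label male. It lay 5.45 above the highest other pool at the probe with the highest mean, and 3 of 4 Xist probes lay at least 1 above every other pool. RNA of female fetuses in that pool is a candidate explanation. X genes that escape inactivation averaged 0.253 above the other 8 pools. They stood at 0.319 in EG in vitro replicate 1 and at 0.297 in EG in vivo replicate 1, a pool that did not detect Xist. Y-linked genes averaged 0.272 above, against -0.279 to 0.217 in the other pools. These averages varied as much between pools without high Xist, and a small share of female RNA would move them little. They cannot argue against female RNA in the pool, which stays open. Without control replicate 1 the calls numbered 7656 in EG in vitro against control and 7376 in EG in vivo against control.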
